A study of Mus musculus with 9 samples.

How the data were processed

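Layer IV of the barrel cortex was laser microdissected from mice at postnatal day 5, and total RNA was purified with RNeasy columns, amplified in a double round of cDNA synthesis and labelled with biotin, per the labels' protocols. Per the labels, 9 mice were used, 3 of each genotype (WT, HZ and KO), and each gave 1 array, so that each array is a separate animal. The mouse array carries 22690 probe sets, of which 64 are controls. The deposited values are linear probe set intensities, made with the MAS5 algorithm in Affymetrix Expression Console per the submitters' processing notes. Versions, filters and the scaling target are not given in the sources used here. In the values themselves, the mean of every array after leaving out the highest and lowest 2% of probe sets was 500.2, so that the authors' intensities had been scaled to 1 common level per array, and no other normalization between arrays was applied before testing. MAS5 signals of dim probe sets are noisy, and such scaling assumes that the bulk of transcripts is alike on all arrays.

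Samples were grouped by the genotype in their titles. Intensities were taken as log2(signal + 16), so that fold changes are on the log2(value + pseudocount) scale and understate the change of dim probe sets. Control probe sets were left out and the 60% of probe sets with the highest mean over all 9 arrays were kept, which left 13576 probe sets and 8503 genes. The lowest mean signal kept was about 117. A linear model with genotype as the only term was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with an intensity trend), giving 6 residual degrees of freedom plus 6.94 from the prior. P-values were adjusted by the Benjamini-Hochberg method over the kept probe sets with a threshold of 0.05. Tests were 2-sided. Gap43 was also compared by 2-sided exact permutation tests, which cannot give a p below 0.1 with 3 arrays against 3. Simulated unchanged groups that shared 3 simulated WT arrays (1000 draws) gave the value that chance alone gives for the correlation of the HZ and KO changes. Correlations with the 3'/5' ratio used permutation tests over 6 relations.

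Probe sets were named with the platform annotation supplied for the arrays. A total of 20393 probe sets had 1 gene symbol, 691 had several, and 1555 that were not controls had none. Of those with 1 symbol, 20364 matched the RefSeq gene table (assembly GRCm38.p6) through their Entrez gene identifier, and 0 symbols needed updating. Probe sets with several symbols were not named. A gene was represented by its probe set of highest mean, and named genes whose probe sets disagreed in direction are said to. The build behind the probe sets is not given in the sources used here, so no coordinates are printed, and the RefSeq table served only for names and for the neighbours of Gap43 on chromosome 16.

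Before the data were examined, 30 gene lists were fixed for the barrel map, synapses, axons, signalling, cortical layers, other cell types, neighbours of Gap43, stress, ribosomes and mitochondria. The 27 lists with at least 5 kept genes were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The estimated correlation was 0.168 for oxidative phosphorylation, 0.269 for astrocyte markers, 0.208 for the growth cone list and 0.173 for ribosomal proteins. It was 0.09 for endothelial and mural markers and 0.0228 for axon guidance. Where genes are correlated above the preset, the preset test gives p-values that are too small. No call held with camera's estimated correlation or with fry, whose main test asks whether the genes of a set move on balance one way. Testing in either direction, fry passed 2 lists for KO against WT, 1 for HZ against WT and 6 for KO against HZ. That test asks whether members changed at all, not whether they changed more than other genes. It was run at the main settings only. The genes named were also fixed by a rule before the data were examined. It took Gap43. For each pair of genotypes it took the 6 largest rises and 6 largest falls past the threshold, with free places going to the genes of smallest p in that direction. It took the 3 members of smallest p in each list that passed, and the member of smallest p in KO against WT in every other list of neurons, synapses, axons or signalling.

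The procedure was tested on simulated data built from the real means and spreads of the 13576 probe sets, with 200 probe sets changed in KO against WT over 10 runs. Of the 100 changed by 2-fold, 79% were recovered on average (69 to 87%), and of the 100 changed by 4-fold 99.5% (98 to 100%), with 5.4% false calls. The simulated HZ against WT, which was left unchanged, gave at most 1 call in a run. In 10 simulations of 8503 genes, a shift of 0.3 on the log2 scale in the axon guidance list was found 10 times, with 1 false list call. These simulations drew genes independently of each other, as the real arrays do not, so they do not test the preset correlation.

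Alternatives were a pseudocount of 1 or 64, quantile normalization, arrays set to 1 median, the replicate number as a block, each array left out, array weights, a sex term, no filter or a stricter one of 40%, no intensity trend, a robust fit, only the 6 arrays of a pair, a threshold of 0.1, the mean of a gene's probe sets, an estimated correlation and fry. A term for the 3'/5' signal ratio of the beta-actin and Gapdh controls and lists without shared genes were added after seeing the data. Sex was read from Xist and a Y-linked transcript. Plots were drawn with matplotlib 3.10.9.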

Results

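Gene expression was measured in layer IV of the barrel cortex, the part of the mouse somatosensory cortex in which thalamic axons carrying whisker input form a map of discrete neuron clusters called barrels. The tissue came from C57BL/6 mice at postnatal day 5 that were wild type (WT), heterozygous (HZ) or knockout (KO) for Gap43, the gene of the growth-associated protein GAP-43, a membrane phosphoprotein of growth cones. Each genotype had 3 mice and each mouse had 1 Affymetrix array, so that 9 arrays with 22690 probe sets each were compared and n = 3 per genotype throughout. The number of arrays limits the precision of every value below. Over the 13576 probe sets tested, arrays of 1 genotype correlated at a median r of 0.963 (range 0.958 to 0.978) across probe sets and arrays of different genotypes also at a median of 0.963 (0.949 to 0.973). Transcripts of the sex chromosomes placed 2 females and 1 male in every genotype. The series addresses whether genes of synapse formation and of the barrel map are altered when GAP-43 is reduced or absent.

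Gap43 was read by 1 probe set. Its scaled signal was 7089, 4746 and 4294 on the WT arrays (mean 5376 ± 1500, SD, n = 3), 5015, 5039 and 4389 on the HZ arrays (4814 ± 368, SD, n = 3) and 979, 1930 and 1299 on the KO arrays (1403 ± 484, SD, n = 3). Gap43 fell 3.85-fold in KO against WT, a log2 change of -1.95 (95% interval -2.44 to -1.45, limma adjusted p = 0.0173), and every KO array lay below every WT array. It fell 3.53-fold in KO against HZ (log2 change -1.82, limma adjusted p = 0.0362). HZ did not differ from WT past the threshold: the signal was 89.5% of WT, a fold of 0.916 with a 95% interval of 0.648 to 1.29 (limma adjusted p = 0.915). In 2-sided exact permutation tests of the log2 values, p was 0.1 for KO against WT, 0.9 for HZ against WT and 0.1 for KO against HZ, and 0.1 is the smallest p that 3 arrays against 3 can give. Among females and between the males, 1 per genotype, the log2 changes were -1.86 and -2.11 for KO against WT, -1.56 and -2.34 for KO against HZ, and -0.30 and 0.22 for HZ against WT, where the sign turned. The labels do not give which part of the gene is deleted, and a probe set outside that part would not check the genotype. The call against WT ended without WT 1 (adjusted p = 0.0694), without WT 2 (0.0513), without HZ 2 (0.0579) or without KO 3 (0.0742), and that against HZ without WT 2 (0.0997), HZ 1 (0.154), HZ 2 (0.174), HZ 3 (0.0672), KO 1 (0.0504) or KO 3 (0.0649). Both calls also ended when the filter was dropped (limma adjusted p = 0.204 against WT and 0.287 against HZ) or the intensity trend was (0.0824 and 0.144). Without WT 1 the HZ value turned to a log2 change of 0.09 against WT.

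**Figure D1:**
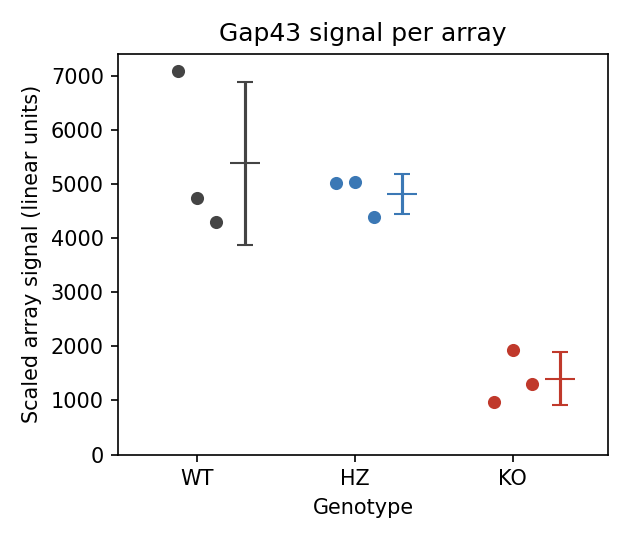
Scaled Gap43 signal in linear units (vertical axis, from 0) for the WT, HZ and KO genotypes (horizontal axis). Each point is 1 array and the horizontal mark with its bar is the mean ± SD of 3 arrays. The KO arrays lie between 979 and 1930, all below the WT and HZ arrays, and the HZ arrays lie between 4389 and 5039, inside the WT range.

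Between KO and WT, Gap43 was the only probe set past the adjusted threshold of 0.05 among the 13576 tested. With an unadjusted p below 0.05 there were 1090 probe sets, 602 higher and 488 lower in KO, where chance alone gives 678.8 on average. Genes are correlated on the arrays, which widens the spread of chance counts around that mean. This count was not scored on other splits of the arrays. No other gene passed, and the genes that follow are those of smallest p in each direction. The lower ones were Gja1, which encodes the gap junction protein connexin 43 of astrocytes, at 2.06-fold (4497 ± 636 in WT and 2185 ± 410 in KO, SD, n = 3, limma adjusted p = 0.114), Arg2, the mitochondrial arginase, at 2.00-fold (adjusted p = 0.114). Also lower were Abhd3 at 2.56-fold, Hsd11b1, a glucocorticoid-activating enzyme, at 2.07-fold and Msrb2, a methionine sulfoxide reductase, at 2.24-fold. All 5 Gja1 probe sets were lower. The higher ones were Erdr1 at 2.32-fold (659 ± 163 in WT and 1533 ± 231 in KO, SD, n = 3, limma adjusted p = 0.114), Sox11, a transcription factor of immature neurons, at 2.38-fold (adjusted p = 0.390). Also higher were Prr3 at 1.72-fold, Ptpru, a receptor tyrosine phosphatase, at 1.67-fold, Mpp3, a membrane scaffold protein, at 1.65-fold and Ctnnd2, the adhesion protein delta-catenin, at 1.47-fold. With array weights in the fit, Arg2, Gja1 and Erdr1 passed (adjusted p = 0.038, 0.0316 and 0.027).

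Of the 27 gene lists tested between KO and WT, 4 passed. Subunits of oxidative phosphorylation, the mitochondrial respiratory chain and ATP synthase, fell as a set. Of 73 measured members 66 were below 0, and the median log2 change was -0.16. Camera gave an adjusted p of 4.54e-09 at the preset correlation of 0.01 and of 0.799 at the estimated correlation of 0.168. The change was small in each gene, with Ndufs3 of complex I at -0.59 ± 0.17 (log2, SE), Uqcr10 of complex III at -0.77 ± 0.26 and Atp5g1 of ATP synthase at -0.38 ± 0.13. No member passed over all genes and 0 passed when adjusted over the list alone. Astrocyte markers fell as a set, with 17 of 24 members below 0 and a median of -0.24 (adjusted p = 0.000717, and adjusted p = 0.834 with an estimated correlation). Gja1 (-1.04 ± 0.16, log2, SE) and S100b (-0.95 ± 0.21), a calcium-binding protein of astrocytes, were lower, whereas Id3, an inhibitor of basic helix-loop-helix factors, was higher (0.69 ± 0.20). None passed over all genes and 4 passed when adjusted over the list alone. Without WT 2 the mean log2 shift moved from -0.17 to -0.11 for oxidative phosphorylation (median -0.10) and from -0.22 to -0.13 for astrocyte markers, which without WT 1 lay at -0.32. The astrocyte call ended without KO 3 (adjusted p = 0.0988, mean shift -0.13 and median -0.16), and neither list passed with fry for a shift one way (adjusted p = 0.28 and 0.64), whereas the astrocyte list passed its test for changes in either direction (adjusted p = 0.00596).

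Axon guidance ligands and receptors rose as a set in KO against WT, with 29 of 38 members above 0 and a median log2 change of 0.15 (camera adjusted p = 0.0209, and adjusted p = 0.799 with an estimated correlation). Plxnb2, a receptor of class 4 semaphorins, was 2.03-fold higher, Sema3e 1.82-fold and Sema4a 1.38-fold. The WT signal of Plxnb2 was dim (89.3 ± 21.7, SD, n = 3), and the WT and KO arrays of Sema3e overlapped. Growth cone and neurite outgrowth proteins, a list that does not hold Gap43 itself, also rose as a set, with 30 of 38 members above 0 and a median of 0.12 (adjusted p = 0.0226, and adjusted p = 0.901 with an estimated correlation). Dpysl5 and Crmp1, of the collapsin response mediator family, were 1.41-fold and 1.23-fold higher, and Tubb3, the neuronal beta tubulin, was 1.26-fold higher. In both lists 0 members passed over all genes and 0 when adjusted over the list alone. With each array's 3'/5' signal ratio as a term, added after seeing the data, the calls ended (adjusted p = 0.0602 and 0.0694). The growth cone call also ended with arrays set to 1 median (0.0577). The 3'/5' ratio can reflect RNA integrity but may also be affected by the double round of cDNA synthesis, and the arrays do not separate them. The call of axon guidance ended without KO 1 (0.152, median 0.09) or KO 2 (0.122). That of the growth cone list ended without WT 1 (0.127, median 0.03), WT 3 (0.141), KO 2 (0.125) or KO 3 (0.508). The growth cone median was 0.20 without WT 2 and 0.18 without KO 1. The mean log2 shift of that list was 0.08 over all arrays, 0.01 without KO 3 and 0.15 without KO 1.

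Lists of the barrel map and of synapses did not pass between KO and WT. Of 25 barrel map genes 15 were above 0 and 10 below (median log2 change 0.03, camera adjusted p = 0.944). Their member of smallest p was Rorb, the transcription factor that marks layer IV neurons, at 530 ± 65.2 in WT and 328 ± 27.4 in KO (SD, n = 3), a log2 change of -0.66 that did not pass over all genes (limma adjusted p = 0.435). It was the 1 member that passed when adjusted over the list alone. Rorb also led the layer IV and upper layer markers, where it was the 1 of 11 members to pass when adjusted over the list alone and the set did not pass (adjusted p = 0.944). Postsynaptic glutamate receptors and density proteins gave an adjusted p of 0.455 and their leading member was Dlg4, the scaffold protein PSD-95, at 2.01-fold higher. Its WT and KO arrays overlapped (217 ± 108 in WT and 429 ± 97.6 in KO, SD, n = 3, limma adjusted p = 0.460). Presynaptic release machinery gave 0.914, led by Syn2, a synaptic vesicle protein whose probe sets disagreed in direction (log2 changes of 0.42 and -0.16). Serotonin signalling, with 5 genes measured, gave 0.19, led by Htr1b, a serotonin receptor present on developing thalamic axons, at 1.42-fold higher. Htr1b was the 1 member to pass when adjusted over the list alone.

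The remaining neuronal and signalling lists did not pass between KO and WT either, and none of their leading members passed over all genes. Cadherins and protocadherins (camera adjusted p = 0.759) were led by Pcdh20 at 1.85-fold lower, with 2 members passing when adjusted over the list alone. Activity-dependent immediate early genes (0.944) were led by Rgs2 at 2.44-fold lower, voltage-gated ion channels (0.944, but 0.00596 with fry for changes in either direction) by Kcnj10, a potassium channel of glia, at 1.55-fold lower, and calcium, calmodulin, protein kinase C and cAMP signalling (0.914) by Gnao1 at 1.34-fold higher. Interneuron markers (0.944) were led by Vip at 1.43-fold lower, GABA-A receptors and inhibitory synapse proteins (0.814) by Gabrd at 1.45-fold lower, and neurotrophins and their receptors (0.914) by Il6st at 1.33-fold lower. Deep layer and subplate markers (0.944) were led by Foxp1 at 1.53-fold higher and striatal and thalamic neuron markers (0.785) by Rora at 1.45-fold lower. In the neurotrophin, voltage-gated channel, interneuron, GABA-A, calcium, deep layer, striatal and thalamic and immediate early lists, 0 members passed when adjusted over the list alone. The lists of extracellular matrix (0.898), progenitor and cell cycle genes (0.619), stress and chaperone genes (0.648) and genes beside Gap43 on chromosome 16 (0.944) did not pass.

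**Figure D2:**
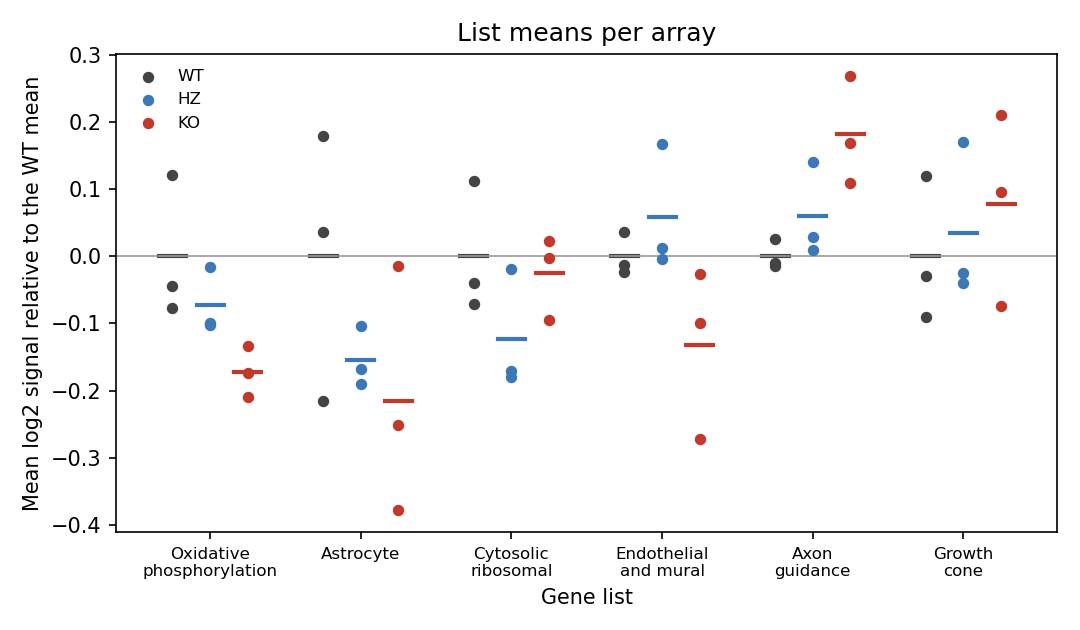
Mean log2 signal of the members of 6 gene lists on each array, relative to the mean of the WT arrays (vertical axis), for the lists that passed in at least 1 comparison (horizontal axis). Each point is 1 array and each bar the mean of 3 arrays. The oxidative phosphorylation means of the KO arrays lie between -0.21 and -0.13, below all WT arrays, and the axon guidance means lie between 0.11 and 0.27, above all WT arrays, whereas the astrocyte and growth cone means of the genotypes overlap.

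Between HZ and WT, 0 probe sets passed (limma, smallest adjusted p = 0.636), with 844 at an unadjusted p below 0.05, 551 higher and 293 lower in HZ. Of the genes of smallest p, Sdhd, a subunit of respiratory complex II, was 2.09-fold lower (1502 ± 100 in WT and 725 ± 175 in HZ, SD, n = 3, limma adjusted p = 0.636). Qtrt1, an enzyme of tRNA modification, was lower 3.10-fold, Apod, the lipid carrier apolipoprotein D, 2.75-fold, Txnl4a, a splicing factor, 1.52-fold and Rpl27a 1.49-fold. Erlec1 was 1.69-fold lower on its brightest probe set (log2 change -0.76) and higher on its other (0.28). On the higher side were Il1f10 at 2.22-fold, Brd8, a bromodomain protein, at 2.17-fold, Sim1 at 1.88-fold, Upk2 at 1.79-fold and Kat6a, a histone acetyltransferase, at 1.61-fold. Htr1b was 1.60-fold higher (383 ± 25.5 in WT and 626 ± 62.8 in HZ, SD, n = 3, limma adjusted p = 0.789). Brd8 passed with array weights (adjusted p = 0.0238) and without WT 2 (0.019), where 2 probe sets passed, and 1 passed without KO 1.

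Of the 27 lists, 3 passed between HZ and WT, and each fell as a set. Cytosolic ribosomal proteins had 34 of 43 members below 0 and a median log2 change of -0.11 (camera adjusted p = 3.05e-05, and adjusted p = 0.888 with an estimated correlation), with Rpl27a at -0.58 ± 0.14 (log2, SE), Rpl8 at -0.38 ± 0.15 and Rpl27 at -0.27 ± 0.12. Oxidative phosphorylation subunits had 52 of 73 members below 0 and a median of -0.07 (adjusted p = 0.00136, and adjusted p = 0.888 with an estimated correlation). Sdhd was lower, whereas the next members by p were higher, Ndufa12 of complex I at 0.41 ± 0.18 and Atp5h of ATP synthase at 0.28 ± 0.12, with its other probe set at -0.22. Astrocyte markers had 17 of 24 members below 0 and a median of -0.17 (adjusted p = 0.00136, and adjusted p = 0.888 with an estimated correlation), led by Glul, the glutamine synthetase of astrocytes, at 1.40-fold lower, Plpp3 at 1.37-fold and Mt2, a metallothionein, at 1.68-fold. For changes in either direction fry passed serotonin signalling alone (adjusted p = 0.0262). No member of the 3 lists passed over all genes, and 1 ribosomal, 1 oxidative phosphorylation and 0 astrocyte members passed when adjusted over the list alone. Without WT 2 none of the 3 calls held (adjusted p = 0.0749, 0.545 and 0.396, with medians of -0.08, 0.01 and -0.11), and without WT 1 the medians of oxidative phosphorylation and astrocyte markers were -0.13 and -0.29. The oxidative phosphorylation call also ended without HZ 1 (0.0696, median -0.05), with quantile normalization (0.401) and with array weights (0.156).

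Between KO and HZ, Gap43 was the only probe set past the threshold, with 1049 probe sets at an unadjusted p below 0.05, 538 higher and 511 lower in KO. Malat1, a long noncoding RNA of the nucleus, was 4.03-fold higher in KO on its brightest probe set and higher on all 4 (1622 ± 660 in HZ and 6687 ± 2651 in KO, SD, n = 3, limma adjusted p = 0.171). Qtrt1 was 3.29-fold higher, Erdr1 2.12-fold and Zcchc7 1.79-fold. Cxcl12, a chemokine, was 2.08-fold higher and Pcbp2, an RNA-binding protein, 1.72-fold, each with a probe set of the opposite direction (log2 changes of -0.13 and -0.02). Besides Gap43, the genes of smallest p on the lower side were Tmem229b at 1.85-fold, Gja1 at 1.84-fold, Rorb at 1.81-fold (609 ± 95.5 in HZ and 328 ± 27.4 in KO, SD, n = 3, limma adjusted p = 0.247) and Pcdh20 at 1.98-fold. Dio2, the deiodinase that activates thyroid hormone, was 2.21-fold lower, with 1 of the 3 Dio2 probe sets higher (0.12). Dio2 passed with the 3'/5' ratio as a term (adjusted p = 0.045) and Malat1 without KO 1 (0.0427). On the scaling of all arrays to 1 median the Gap43 call ended (adjusted p = 0.0878), as it did with quantile normalization (0.0796).

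Of the 27 lists, 5 passed between KO and HZ. Endothelial and mural cell markers fell as a set, with 19 of 22 members below 0 and a median log2 change of -0.21 (camera adjusted p = 0.0261, and adjusted p = 0.783 with an estimated correlation), led by Bsg, Ramp2 and Egfl7 at 1.25-fold lower each. Oxidative phosphorylation subunits fell with 54 of 73 below 0 and a median of -0.08 (adjusted p = 0.0334, and adjusted p = 0.783 with an estimated correlation). Ndufa7 was 1.61-fold and Uqcr10 1.62-fold lower, and Sdhd was 1.54-fold higher. Cytosolic ribosomal proteins rose, with 30 of 43 above 0 and a median of 0.07 (adjusted p = 0.0261, and adjusted p = 0.783 with an estimated correlation), led by Rpl27a at 1.49-fold, Rps25 at 1.54-fold and Rpl8 at 1.25-fold higher. Axon guidance genes rose, with 24 of 38 above 0 and a median of 0.08 (adjusted p = 0.0334, and adjusted p = 0.783 with an estimated correlation), led by Robo1, a Slit receptor, at 2.10-fold, Epha3, an ephrin receptor, at 1.56-fold and Plxnb2 at 1.90-fold higher. Growth cone proteins rose, with 25 of 38 above 0 and a median of 0.07 (adjusted p = 0.029, and adjusted p = 0.783 with an estimated correlation). Tubb2b was 1.29-fold and Tubb3 1.26-fold higher, and Dpysl3 was 1.16-fold higher, with 1 of its 3 probe sets lower (log2 change -0.09). In these 5 lists 0 members passed over all genes, and only 1 ribosomal member passed when adjusted over the list alone.

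Tested by fry for changes in either direction, 6 lists passed between KO and HZ. They included the layer IV and upper layer markers (adjusted p = 0.00372), in which Rorb was lower, the barrel map genes (0.0319), in which Rorb was lower and Robo1 higher, and axon guidance (0.00758). The others were astrocyte markers (0.00338), cadherins and protocadherins (0.0491) and stress and chaperone genes (0.0319). Of the 24 astrocyte markers 12 were above 0 and 12 below, with Gja1 among the lower. Of the 22 cadherins and protocadherins 13 were above 0 and 9 below, with Pcdh20 among the lower. Of the 6 lists only axon guidance also passed with camera. Camera's adjusted p was 0.545 for the layer IV list and 0.94 for the barrel map. Unlike the camera calls, these fry calls were not rerun without an array, under other settings or on other splits of the arrays.

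Of the camera calls between KO and HZ, that of the growth cone list ended in 5 of the 9 fits without an array (adjusted p = 0.0547 without WT 3, 0.2235 without HZ 1, 0.2955 without HZ 3, 0.1035 without KO 2 and 0.365 without KO 3), axon guidance in 4 (0.151 without HZ 1, 0.259 without HZ 3, 0.334 without KO 1 and 0.1035 without KO 2), the ribosomal list in 4 (0.151 without HZ 1, 0.0918 without HZ 2, 0.1395 without KO 2 and 0.0505 without KO 3), oxidative phosphorylation in 3 (0.0547 without WT 3, 0.2955 without HZ 3 and 0.429 without KO 1) and the endothelial list in 2 (0.151 without HZ 1 and 0.1035 without KO 2). Without 1 array the axon guidance median ranged from -0.02 (without KO 1) to 0.14 (without HZ 2). The ribosomal median ranged from 0.01 (without HZ 1) to 0.13 (without HZ 3). The growth cone median ranged from 0.04 (without HZ 1) to 0.14 (without HZ 2). The mean log2 shift of the growth cone list was less stable, at 0.04 over all arrays and 0.12 without KO 1. It was 0.005 without HZ 3 and turned to -0.02 without KO 3. Calls also ended without the filter on dim probe sets (endothelial 0.0529, oxidative phosphorylation 0.058, axon guidance 0.0561 and growth cone 0.0529), with quantile normalization (ribosomal 0.435 and growth cone 0.297), with arrays set to 1 median (axon guidance 0.0689 and oxidative phosphorylation 0.0902), with the mean of a gene's probe sets (axon guidance 0.108, growth cone 0.109 and endothelial 0.106) and with genes of 1 list only (axon guidance 0.171).

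In the test over all 3 genotypes, 1 probe set passed (limma moderated F-test, smallest adjusted p = 0.0211) and 1025 had an unadjusted p below 0.05. In the test of HZ against the midpoint of WT and KO on the log2 scale, 0 probe sets passed (limma, smallest adjusted p = 0.4, and 909 at an unadjusted p below 0.05). Across 8503 genes, which are not independent replicates, the log2 changes of HZ against WT and of KO against WT correlated at r = 0.47. Unchanged groups simulated with 3 shared WT arrays gave a mean r of 0.45 (95% of simulations between -0.32 and 0.91). The covariance was 0.0306, within the simulated range of -0.00843 to 0.0758, and exceeded the simulated mean of 0.0244 by 0.00626. The SD of the simulated covariance was 0.0223, and a share of 0.554 of the simulations gave an r as high. No effect shared by HZ and KO could therefore be told apart from the sharing of the WT arrays. The WT arrays were not split, since 3 arrays do not give each part 2. As HZ against WT had 0 calls, no overlap of calls could be formed. For the difference between the sexes in the effect of KO and of HZ against WT, 0 probe sets passed in each case (limma, with 458 and 292 at an unadjusted p below 0.05), a test with 1 male per genotype that leaves such differences open. Sex itself, as a term beside genotype, gave 2 probe sets past the threshold, both of Xist.

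Markers of layers and other cells of the captured tissue were measured beside these comparisons. The layer lists differed between arrays of 1 genotype. Relative to the WT mean, layer IV and upper layer markers lay at 0.23 on KO 1 and -0.18 on KO 3 (log2). Deep layer and subplate markers lay at -0.32 and 0.30 there. On WT 1 and WT 3 the values were -0.10 and 0.17 for the first list and 0.18 and -0.22 for the second. On KO 2 both were above 0 (0.02 and 0.07). Whether the captured layers differed was not tested. Microglia markers had 8 of 11 members below 0 in KO against WT (median log2 change -0.23, camera adjusted p = 0.305), oligodendrocyte lineage markers 8 of 15 (-0.08, adjusted p = 0.455), endothelial and mural markers 16 of 22 (-0.10, adjusted p = 0.0641) and meningeal and fibroblast markers 7 of 15 (0.00496, adjusted p = 0.944). In KO against HZ, where the endothelial and mural list passed, oligodendrocyte lineage markers had 11 of 15 members below 0 (-0.27, adjusted p = 0.12), microglia markers 8 of 11 (-0.21, adjusted p = 0.49), striatal and thalamic neuron markers 10 of 12 (-0.15, adjusted p = 0.179) and meningeal and fibroblast markers 7 of 15 (0.07, adjusted p = 0.545), and none of these passed. The lists of red blood cell, choroid plexus and sex-linked transcripts kept 4, 4 and 3 genes and were not tested. The 3'/5' signal ratio of the beta-actin control was 25.1 on HZ 2 and between 7.8 and 12.4 on the other arrays, and that of the Gapdh control was 27.9 on HZ 2 and between 11.5 and 19.5 elsewhere. Over the 9 arrays the ratio did not correlate with the mean of any of the 6 lists that passed in a comparison. For oxidative phosphorylation Pearson's r was -0.04 (permutation p = 0.912, adjusted p = 0.912 over 6 relations) and Spearman's rho -0.32 (permutation p = 0.409), and without HZ 2 and WT 2, the arrays farthest from the median ratio, r was -0.89. For axon guidance r was 0.48 (permutation p = 0.191, adjusted p = 0.572) and rho 0.57 (permutation p = 0.121), with 0.88 without those arrays. For the growth cone list r was 0.59 (permutation p = 0.0785, adjusted p = 0.471) and rho 0.57 (permutation p = 0.12), with 0.30 without them. For astrocyte markers r was 0.13 (permutation p = 0.731, adjusted p = 0.877) and rho 0.13 (permutation p = 0.744), with -0.02 without them. For ribosomal proteins r was -0.17 (permutation p = 0.653, adjusted p = 0.877) and rho 0.10 (permutation p = 0.81), with 0.33 without them. For endothelial and mural markers r was -0.25 (permutation p = 0.452, adjusted p = 0.877) and rho -0.52 (permutation p = 0.162), with -0.78 without them.

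**Figure D3:**
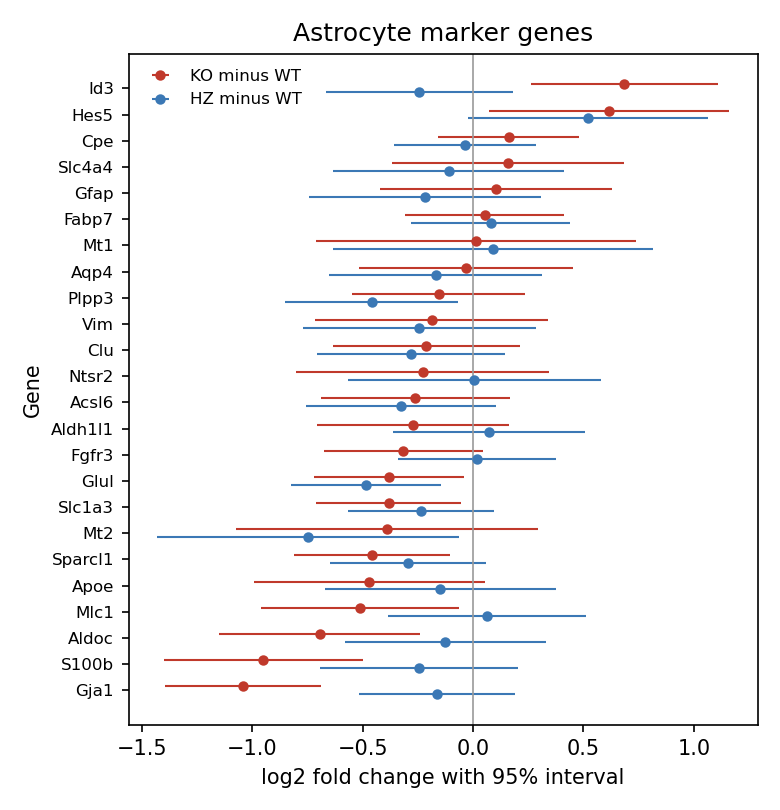
Log2 fold change (horizontal axis) of the 24 measured astrocyte marker genes (vertical axis, ordered by the KO value) in KO minus WT and HZ minus WT. Points are estimates of the fit over 9 arrays and bars their 95% intervals. Gja1 and S100b lie lowest in KO minus WT (-1.04 and -0.95), and the intervals of Id3 and Hes5 lie above 0.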

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

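The 3'/5' ratio term and the lists without shared genes were chosen after seeing the data, and the other alternatives before. The replicate number was not a pairing: arrays of the same number deviated together at a median r of -0.01 (-0.26 to 0.11) and 3 of 9 arrays correlated best with their own number. With the replicate block, calls went from 1 to 2 between KO and HZ (Gap43 and Malat1, adjusted p = 0.027) and from 1 to 0 over all genotypes. With array weights 5 probe sets passed between KO and WT (Gap43, Gja1, Erdr1 and both Arg2 probe sets), 3 between HZ and WT (Abcf1, Brd8 and Gpaa1, the first and last named after their values were seen) and 5 over all genotypes. Without the filter, and without the intensity trend, 0 passed between KO and WT, 0 between KO and HZ and 0 over all genotypes; Gap43 then stayed at -1.946 against WT (adjusted p = 0.204 and 0.0824) and -1.82 against HZ (0.287 and 0.144). With quantile normalization and with arrays set to 1 median, 0 passed between KO and HZ and 0 over all genotypes, with Gap43 at -1.837 (adjusted p = 0.0796) and -1.79 (0.0878). With the 6 arrays of the pair alone, 0 passed for KO against WT and 0 for KO against HZ, a fit with 4 residual degrees of freedom. At the threshold of 0.1, 2 passed between KO and HZ. With the 3'/5' ratio term 3 passed between KO and HZ (Gap43, Dio2 and Polr2f, the last named after its value was seen) and 0 over all genotypes. The cause of these changes was not tested.

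Leaving out each array in turn, where an arm of 2 arrays shares the spread of the others, gave 0 to 2 probe sets for KO against WT, 0 to 2 for HZ against WT, 0 to 2 for KO against HZ, 0 to 3 over all genotypes and 0 to 2 off the midpoint. The Gap43 change was -2.202 to -1.718 for KO against WT (adjusted p 0.0045 to 0.0742), -2.075 to -1.592 for KO against HZ (0.00839 to 0.174) and -0.2709 to 0.08966 for HZ against WT, the sign turning without WT 1. Gpaa1, named after its values were seen, was called without WT 2 (2.33 for KO and 2.52 for HZ against WT). The correlation of the HZ and KO changes was 0.3687 to 0.6. List calls were 2 to 5, 0 to 3 and 2 to 5 for KO against WT, HZ against WT and KO against HZ. They were 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry. The 3'/5' ratio term gave 2 lists for KO against WT; for KO against HZ there were 3 with quantile normalization, 3 with 1 median, 1 without the filter and 2 with the mean of a gene's probe sets. The oxidative phosphorylation call of KO against WT held in all 9 fits without an array and in the 11 other settings run with the preset correlation (highest adjusted p = 0.00291, without WT 2, where the mean shift moved from -0.173 to -0.112). Of the named genes other than Gap43, 1661 values under 21 settings all had the direction reported, and 8 were past the threshold. These genes had been picked by small p in the same 9 arrays. Their direction was thus unlikely to turn, and the count is not a test of them. No other Gap43 probe set exists on this array, so that alternative was not run. Dim probe sets are limited by background: the filter removes those with a mean signal below about 117.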

Other observations

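The tests of the astrocyte, oxidative phosphorylation and Gap43 patterns were chosen after those patterns were seen. The count of astrocyte members above 0 and the check without HZ 2 and WT 2 were also chosen after their own values were seen. So were the genes of this paragraph, except Rorb and Robo1, which the fixed rule had named between KO and HZ. Some lists that did not pass as sets held members that passed when adjusted over the list alone, with none passing over all genes. Between KO and HZ, 3 of 25 barrel map genes did so: Rorb and the glutamate receptor subunit Grin2b were lower in KO (log2 changes of -0.86 and -0.74) and the Slit receptor Robo1 was higher (1.07). Among the layer IV and upper layer markers 2 of 11 did, Rorb and Cux1 (-0.76), both lower in KO, and 2 of 22 cadherins and protocadherins did. So did 3 of 24 astrocyte markers, 2 of 29 immediate early genes and 2 of 24 stress and chaperone genes. These adjustments were made within each list and not over the 27 lists. Rorb counts in both the barrel map and the layer IV list. Among the astrocyte markers, the lower members in KO against WT included Aldoc (-0.70), Sparcl1 (-0.46), Slc1a3 (-0.38), Mlc1 (-0.51) and Glul (-0.38).

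The lower astrocyte markers in KO were set against 3 explanations. As far as the 3'/5' ratio reads RNA degradation, a difference between arrays would have taken at least 50% of the shift when the ratio entered as a term. The mean log2 shift was -0.2256 with the term and -0.215 without it, keeping 105% (SE 7.81), but HZ 2 and WT 2 set the slope of this test: without them it was -0.34 with the term and -0.13 without it, keeping 273% (SE 141), too imprecise to decide, so degradation cannot be told apart from genotype here. A scaling that depends on signal level gave 0 of 10000 random lists matched on mean signal with a median as low, which argues against it. Fewer astrocytes in the captured tissue may account for it and cannot be told apart from lower expression within them, as the arrays measured tissue and not single cells. Of the 24 members, 2 had a 95% interval above 0, Id3 and Hes5, while 7 lay below. Unchanged genes would give 0.6 above 0 (binomial p = 0.12). A loss of astrocytes would give fewer than unchanged genes do, so this count does not decide the question. A change of astrocyte state in KO also stays open, untested.

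The lower oxidative phosphorylation subunits in KO were weighed in the same way. A scaling that depends on signal level gave 0 of 10000 matched random lists with a median as low, which argues against it. With the 3'/5' ratio as a term over 9 arrays the mean log2 shift was -0.1738 against -0.173 without it, so that by this test degradation would not account for the shift. That test rests on HZ 2 and WT 2, which set the slope: without them the shift was -0.11 and with the term -0.06, keeping 51.5% (SE 40.9), so degradation cannot be told apart from genotype for this list. An effect of genotype on mitochondrial transcripts stays open beside it.

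Gap43 in HZ lay near WT rather than near 50% of it. Saturation of the probe set stays open: 147 probe sets had a mean WT signal of 2 times that of Gap43 or more, but probe sets differ in affinity, so this test does not decide it. A background signal equal on all arrays would put HZ at the midpoint of WT and KO, but HZ was 1.457 times the midpoint (95% interval 1.06 to 2.00). Transcription or stability of the remaining copy that makes up for the missing one stays open beside saturation as a candidate explanation that was not tested. The HZ labels rest on titles alone, as the signal of this probe set does not separate HZ from WT.

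Other splits of the arrays were fitted in the same way. For each pair of genotypes there are 10 splits of 6 arrays, too few for a share under 0.05. As many probe sets as in the real split came from 2 of 10 splits for KO against WT (real 1, highest other 1), 10 of 10 for HZ against WT (real 0, highest other 0) and 5 of 10 for KO against HZ (real 1, highest other 1). As many lists came from 5 of 10 for KO against WT (real 4, highest other 9), 6 of 10 for HZ against WT (real 3, highest other 4) and 2 of 10 for KO against HZ (real 5, highest other 6). Over all genotypes 19 of 100 drawn splits gave at least the real count of 1 (highest other 4), so chance was not excluded. Off the midpoint 100 of 100 gave at least the real 0 (highest other 5), which a count of 0 fixes and which tests nothing.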
